A study of Mus musculus with 278 samples.

How the data were processed

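The deposited data are single-cell RNA-seq libraries of spermatogonia from 6-day-old mice that carry an EGFP reporter of Id4, a gene of the inhibitor of DNA binding family expressed in spermatogonial stem cells. Each of the 278 samples is 1 cell. Per the labels' protocols, EGFP-positive cells were isolated from pooled testes, captured on a Fluidigm C1 microfluidic chip, and imaged for EGFP brightness. Libraries were made with SMARTer cDNA synthesis and Nextera tagmentation. Wells with dead cells, multiplets or debris were left out after imaging. The labels place every cell in 1 of 4 quartiles of EGFP brightness, from Q1 (bright) to Q4 (dim). A passage in the protocols numbers the dim quartile differently, and the order used here is the one in the design text.

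The deposited matrix gives 1 value per gene and cell in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the cell). The unit was read from the name of the quantifier and from the values, since the file header does not state it. Per the submitters' processing notes, FastQC, TopHat, Cufflinks and Picard and the mouse genome mm10 (GRCm38) were used; versions, settings and annotation are not given in the sources used here. FPKM are not counts, so no count model was used. Reads shared by near-identical copies or by genes that overlap may be split between them by the quantifier, and no statement on strand is given in the sources used here.

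The matrix holds 23354 genes, of which 6247 are listed at 0 in every cell, and all of its 278 columns were used. Of the gene symbols, 21695 were matched to the GENCODE M21 annotation of GRCm38, from which coordinates and overlaps were taken. Transcripts of EGFP, of spike-ins and of the mitochondrial genome were not analysed here.

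Depth is not stated, so it was estimated from the smallest steps between low FPKM values of 2110 genes with 1 annotated transcript of at least 1500 bases. The estimate was 624541 mapped fragments per cell at the median, with a range of 203649 to 1240822. In 253 of 278 cells the estimates from 2 separate sets of these genes lay within 1.25-fold of each other. Of the low values compared, 5756 lay at the estimated step of 1 fragment and 351 between steps. The estimate was chosen for such a contrast, so these counts are no separate check of it. On 20 simulated libraries the largest error was 0.782%. These were built from whole fragments and the same transcript lengths that the estimate assumes, so this is not its error in the real cells. If the authors rescaled their values, the estimate is an effective depth. Whole reads could not be recovered for genes with several transcripts. An exact 0 can be a missed molecule or a failed estimate: Gapdh, with a median of 27.8 FPKM, was listed at 0 in 1 cell, while Actb, Eef1a1, Rps3, Ubb and Hsp90ab1 were listed at 0 in no cell.

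Cells were not treated as replicates. The sample titles carry a run number from 1 to 5, taken here as the number of the cell preparation, and the mean over cells of log2(FPKM + 1) was computed for each of the 20 combinations of preparation and quartile. The preparation is therefore the unit of replication (n = 5), and each quartile of a preparation comes from the same cell suspension. The labels do not say whether preparations came from separate litters. Quartiles were compared within preparations. For single genes, p-values weigh a difference against the spread of the means of all quartiles around the fit, the sampling of cells included. In limma this spread is also drawn toward that of other genes of similar expression. Such p-values therefore do not measure only how evenly the differences between a given pair of quartiles repeat over preparations. The numbers pair the means: over the 30 pairs of means from the same preparation, deviations from the quartile means had a median correlation across genes of 0.19 and a lowest of 0.08, against a median of -0.07 between preparations. No 2 cells were duplicates (highest correlation between cells across genes 0.808).

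Genes at FPKM of at least 1 in at least 10% of cells were kept, which left 10452. The 20 means were fitted with limma (3.58.1, in R 4.3.3 with data.table, version 1.17.8; trend = TRUE), weighted by their number of cells, with 4 quartile levels and preparation as a block, which left 12 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. Q1 was compared with Q4, each quartile with the next, and a linear trend over the quartiles was tested as the slope per quartile step toward Q1. All differences are on the log2(FPKM + 1) scale, with a pseudocount of 1, which understates changes of low genes. Gene lists were fixed before the data were examined. The 28 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists. Lists of Leydig, peritubular myoid, stromal and macrophage markers had 2 tested members each, and the erythroid list 0, so they were described and not tested. A relative median is the median log2 difference of a list minus that of all tested genes. Detected genes per cell (FPKM of at least 1) were compared by an exact two-sided permutation test that flips the signs of the 5 differences within preparations; its 32 assignments allow no p below 0.063.

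The rule for named genes was set before the data were examined. It always takes Id4, Gfra1, Etv5, Nanos2, Neurog3, Zbtb16, Sohlh1, Kit and Stra8, members of the lists that passed the test over all genes, and up to 8 genes per direction with the largest difference that passed and had the same sign in all 5 preparations, leaving out predicted genes and clone names. For each comparison it adds the 3 genes with the smallest p in each direction. An item that this rule takes is not reported here. Other genes named, among them 9430023L20Rik, list members adjusted over the list alone and neighbours of Upf3b, were chosen after their values were seen.

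The fit was tested on simulated data: quartile labels were reassigned among the cells of each preparation in 10 runs over the same 10452 genes, and 500 genes per fold size over all runs were multiplied in Q1 or Q4. For Q1 against Q4, limma recovered 10% of genes changed 2-fold, 31% at 4-fold, 52.6% at 8-fold and 65.6% at 16-fold, with 33 false calls among 102300 unchanged genes. Values of 0 stayed 0 when multiplied, so changes in the share of cells that detect a gene were not simulated. A list of 22 genes raised 2-fold was called in 10 of 10 runs, and 0 of 270 unchanged lists of random genes were called at an adjusted p under 0.05. For the 28 real lists, with labels reassigned 100 times in the same way, a median of 1 list and at most 5 were called.

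Alternatives were set before the data were examined: a pseudocount of 0.1, no filter or a filter at 25% of cells, the log of the mean over cells, rescaling each cell to a common total or to a common 75th percentile, equal weights, no preparation block, the number of detected genes as a covariate, leaving out the 4 cells with fewer than 3160 detected genes, leaving out each preparation in turn, and fitting only the quartiles compared. Matching Q1 and Q4 cells within preparations on detected genes (within 300 genes), leaving out the low cells from the comparison of detected genes, leaving out 1 cell rich in Sertoli cell transcripts, and shortening 1 gene list were added after seeing the data. Depth estimates and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.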

Results

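Single-cell expression profiles were collected from 278 Id4-EGFP positive spermatogonia of mice at postnatal day 6, an age at which spermatogonial stem cells, progenitors and the first differentiating spermatogonia share the seminiferous cords. Because Id4 reporter brightness has been used to grade these cells, the cells were grouped by EGFP quartile: 74 in Q1 (bright), 70 in Q2, 74 in Q3 and 60 in Q4 (dim). They came from 5 preparations of 26, 62, 37, 75 and 78 cells, each with cells of all 4 quartiles, from 4 cells (preparation 1, Q4) to 20. The germ cell genes Ddx4, Dazl, Mael and Uchl1 were at FPKM of at least 1 in 100% of cells, and the cell with the fewest of the 13 germ cell markers had 6 (median 12).

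Mean detected genes per cell were 6293 ± 931 in Q1, 6173 ± 1047 in Q2, 6106 ± 1127 in Q3 and 5732 ± 1305 in Q4 (SD of 5 preparation means, n = 5). The estimated depth was 603796 ± 121972 mapped fragments per cell in Q1, 643340 ± 114482 in Q2, 591295 ± 148325 in Q3 and 581388 ± 165886 in Q4 (SD, n = 5). Q1 cells had 561 ± 379 more detected genes than Q4 cells (SD, n = 5), from 178 to 1071, and more in 5 of 5 preparations (exact permutation test, two-sided, p = 0.063, the smallest p that 5 preparations allow). Depth did not differ beyond the spread between preparations: the log2 ratio of fragments, Q1 to Q4, was 0.09 ± 0.18 (SD, n = 5), above 0 in 3 of 5 preparations (exact permutation test, two-sided, p = 0.4375). Preparation 3 had 4437 detected genes per cell, against 5875 to 7148 in the other preparations.

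**Figure D1:**
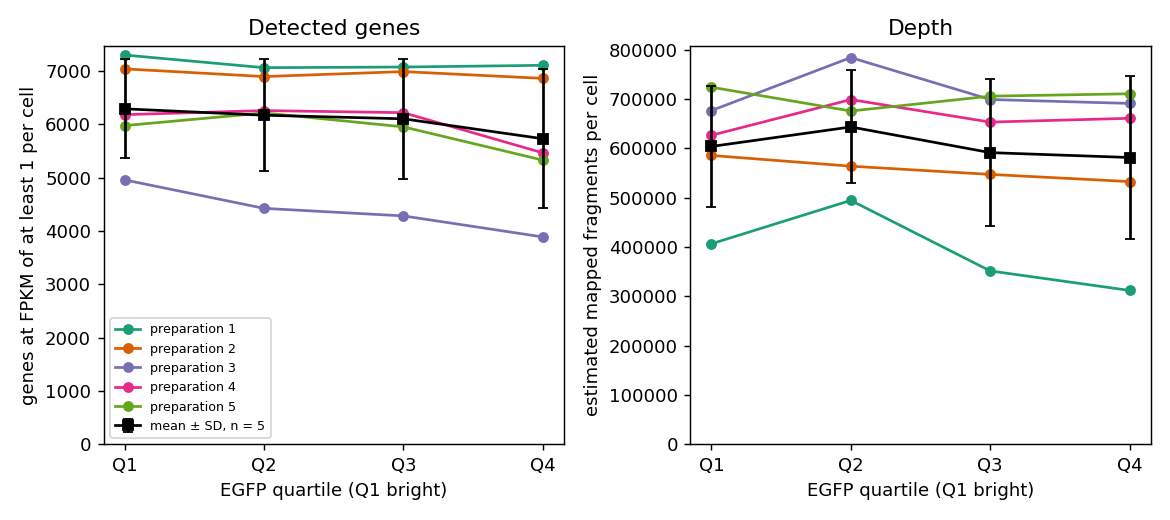
Detected genes per cell (left, genes at FPKM of at least 1) and estimated mapped fragments per cell (right) by EGFP quartile; coloured lines are the 5 preparations, and black squares with bars are their mean ± SD. Detected genes were lower in Q4 than in Q1 in all 5 preparations, and preparation 3 had the fewest.

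The comparison of Q1 with Q4 asked how the brightest cells differ from the dimmest. In Q1, 2 gene lists known from spermatogonial stem cells stood higher relative to all genes: markers associated with stem cells, with a relative median of 0.45 on the log2 scale (22 genes), and genes that respond to GDNF or FGF, the growth factors that maintain these cells, with 0.63 (20 genes). Both were higher in 5 of 5 preparations (camera adjusted p = 2.79e-08 and 1.70e-08), and both calls held with an estimated correlation (adjusted p = 0.0342 for each list). Single genes that rose in Q1 included Upf3b, a nonsense-mediated decay factor (2.27 ± 0.41, log2 difference ± SE, limma adjusted p = 0.0361). Others were Snrpn, an imprinted gene for a spliceosomal protein (2.16 ± 0.39, limma adjusted p = 0.0361), Capg, an actin-capping protein (1.93 ± 0.35), and Hlf, a PAR bZIP transcription factor (1.68 ± 0.30; n = 5 preparations). Cytosolic ribosomal protein genes stood lower in Q1 relative to all genes at the preset correlation, with a relative median of -0.31. That call was lost with an estimated correlation (adjusted p = 0.0562) and with detected genes as a covariate (-0.08, adjusted p = 0.31).

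Altogether 8 of 10452 genes passed the limma test, all of them higher in Q1. At an unadjusted p under 0.05 there were 1192 genes, 1084 higher and 108 lower in Q1, where chance gives 522.6, and the median difference over all genes was 0.17. Upf3b averaged 80.8 ± 34.3 FPKM in Q1 and 36.9 ± 20.7 in Q4 (SD, n = 5), and the share of cells at FPKM of at least 1 was 84.3% against 47.9%; its 5 differences within preparations ran from 1.82 to 2.66. Capg averaged 116 ± 20.4 and 60.2 ± 33.2 FPKM, and its differences within preparations were less even, from 0.44 to 2.87. Hlf averaged 9.54 ± 2.96 FPKM over Q1 cells and 1.71 ± 0.90 over Q4 cells, and was at FPKM of at least 1 in 73.1% and 22.5% of them. Snrpn averaged 28.7 ± 15.4 FPKM in Q1 and 6.26 ± 6.17 in Q4, with differences within preparations from 1.12 to 4.04. Snurf (1.95 ± 0.37, adjusted p = 0.0399) is encoded by the same transcripts as Snrpn, so the pair cannot be counted as separate genes. Nefm, a neurofilament subunit (1.84 ± 0.35), and Rab4a, a GTPase of recycling endosomes (1.48 ± 0.29), had the same adjusted p. Rab4a was at FPKM of at least 1 in 41.8% of Q1 cells and 6.67% of Q4 cells. All 7 of these were higher in 5 of 5 preparations. The unnamed transcript 9430023L20Rik (2.15 ± 0.42, limma adjusted p = 0.0399), chosen after its values were seen, was higher in 4 of 5. Its differences within preparations ran from -0.07 to 4.65. No gene passed at the lower end, where genes of small p included Eif4ebp1, an inhibitor of cap-dependent translation (-0.76 ± 0.19, limma adjusted p = 0.136), and Cox4i1 of cytochrome c oxidase (-0.26 ± 0.07), each lower in Q1 in 5 of 5 preparations.

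The calls of single genes were lost in several settings. Without the preparation block limma called 0 genes (592 at an unadjusted p under 0.05), with detected genes as a covariate 0 (563), and with only the cells of Q1 and Q4 in the fit 0 (1074). Without preparations 1, 4 or 5 it called 0 (1091, 989 and 932), without preparation 3 it called 2, and without preparation 2 it called 11. With each preparation left out in turn the difference of Upf3b ran from 2.13 to 2.42, that of Hlf from 1.56 to 1.80, Nefm from 1.72 to 2.09, Rab4a from 1.36 to 1.59, Snrpn from 1.82 to 2.49 and Capg from 1.59 to 2.38. The other alternatives, some of which change the scale, moved the sizes more. Upf3b ran from 1.16 to 3.41, Hlf from 1.37 to 2.91 and Nefm from 1.23 to 3.07. Rab4a ran from 1.48 to 2.52, Snrpn from 1.47 to 3.47 and Capg from 1.07 to 2.68.

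On GRCm38, Upf3b lies on chromosome X at 37091678 to 37110322, Snrpn on chromosome 7 at 59982495 to 60140219, Capg on chromosome 6 at 72544391 to 72562983, Nefm on chromosome 14 at 68082590 to 68124846, Hlf on chromosome 11 at 90336536 to 90390895 and Rab4a on chromosome 8 at 123805985 to 123835287. All are protein coding, and their values are the quantifier's FPKM per gene. Snurf lies within Snrpn, at 59995449 to 60005049, and shares its exons. Exons of Nefm overlap Nefl on the opposite strand, so its value is uncertain where strand was not used. The same holds for Id4 (chromosome 13, 48261228 to 48266026; A330033J07Rik and Gm49291), Gfra1 (chromosome 19, 58235604 to 58455909; Gm16277), Nanos2 (Gm45058) and Neurog3 (Fam241b). Exons on the opposite strand also overlap those of Snrpn, Bmpr1a, Cd9, Cetn4, Cox4i1, Dedd, Dusp1, Pdha1, Ptbp3, Rfc2, Rnd2, Spry1 and Uchl1. Arhgef3 and Hipk3 share exonic bases with another gene on the same strand.

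Of the genes fixed in advance, Id4 itself averaged 17.4 ± 9.57 FPKM in Q1 and 3.77 ± 4.53 in Q4 (SD, n = 5) and was higher in Q1 in 5 of 5 preparations, but 1.61 ± 0.41 did not pass over all genes (limma adjusted p = 0.138). Gfra1, the GDNF co-receptor (1.93 ± 0.43, adjusted p = 0.0858), and Etv5, an ETS factor induced by GDNF (1.62 ± 0.39, adjusted p = 0.107), were higher in 4 of 5 preparations and did not pass. Over the alternatives Gfra1 ran from 0.57 to 3.11 (limma adjusted p from 0.0291 to 0.894). Etv5 ran from 0.56 to 2.63 (limma adjusted p from 0.0404 to 0.922). Nanos2, an RNA-binding protein of undifferentiated spermatogonia, differed by 0.40 ± 0.22 and Zbtb16, a transcription factor of undifferentiated spermatogonia, by 0.50 ± 0.30. Neurog3, a progenitor marker, differed by -0.47 ± 0.22, with no preparation higher in Q1, and the differentiation genes Sohlh1, Kit and Stra8 by -0.36 ± 0.31, -0.03 ± 0.39 and -0.48 ± 0.47. None of these 6 passed (limma adjusted p from 0.427 to 0.988).

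**Figure D2:**
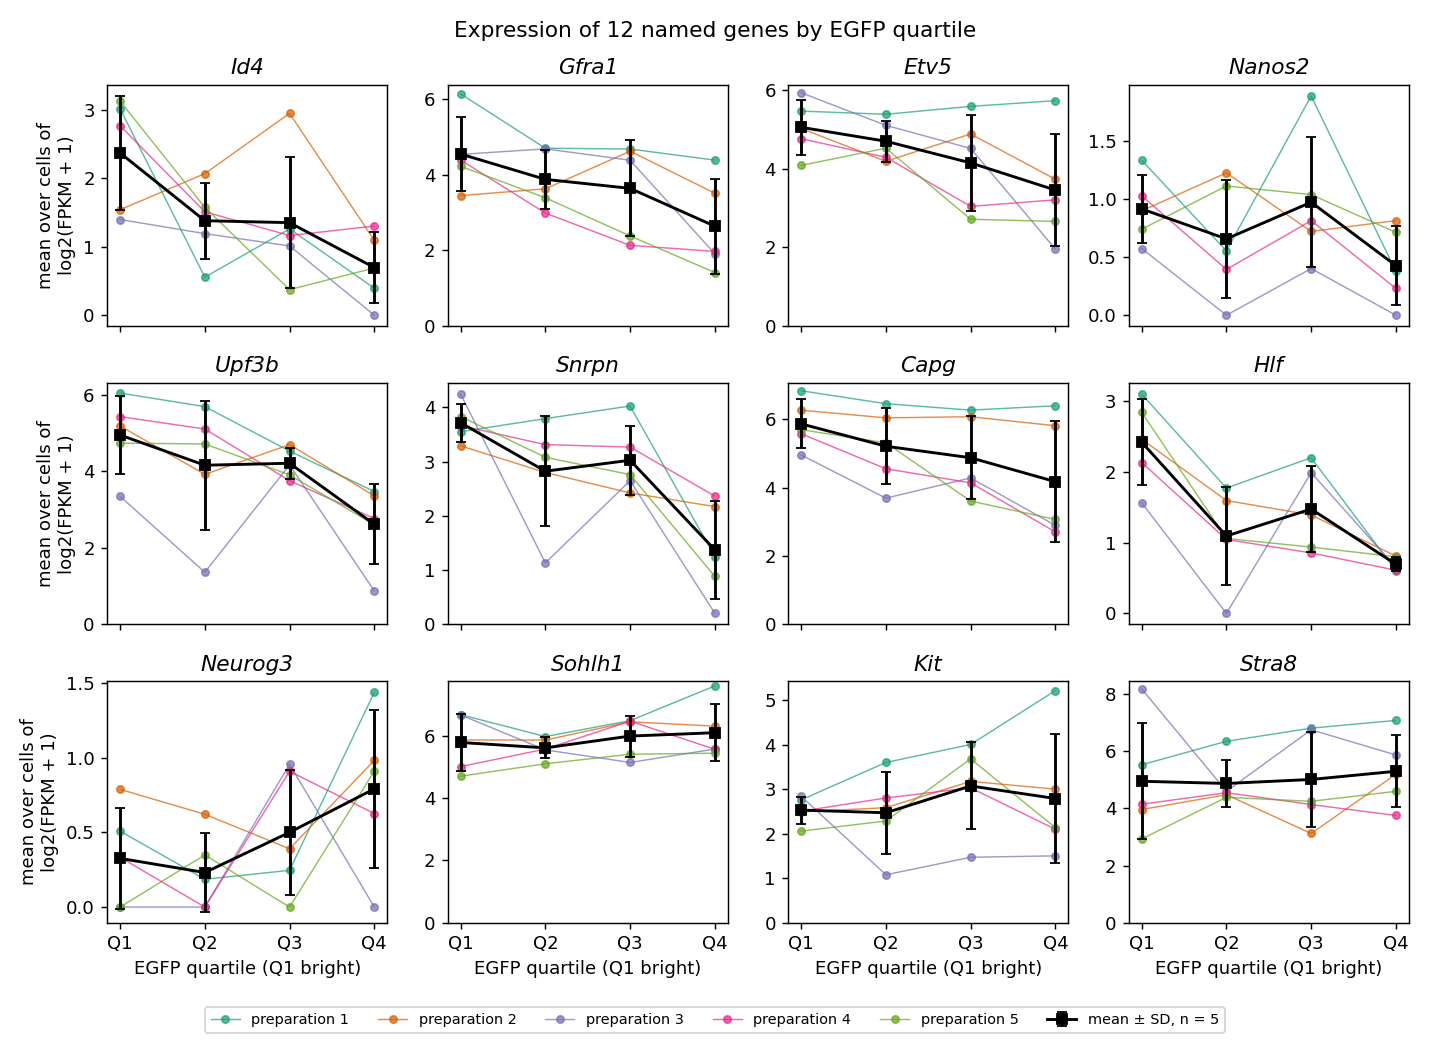
Mean over cells of log2(FPKM + 1) for 12 named genes (y axis) in each EGFP quartile (x axis, Q1 bright); coloured lines are the 5 preparations, and black squares with bars are their mean ± SD. Upf3b, Snrpn, Capg and Hlf passed the test of Q1 against Q4, while Id4 (1.61), Gfra1 (1.93), Etv5 (1.62) and the other genes shown did not.

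Among the 22 tested stem cell associated genes, 10 passed when adjusted over the list alone and 0 over all genes (limma; 12 at an unadjusted p under 0.05). They were Tcl1, a coactivator of AKT kinases (2.40 ± 0.49), Gfra1, Dusp6, Etv5, Id4, the adhesion molecule Cdh1 (1.04 ± 0.29), Egr2, Bcl6b, the GDNF receptor Ret (1.04 ± 0.37) and the tetraspanin Cd9 (0.71 ± 0.25). Of the 20 GDNF or FGF response genes, 10 passed adjusted over the list alone and 0 over all genes (limma; 14 at an unadjusted p under 0.05). These included the ERK phosphatase Dusp6 (1.82 ± 0.41), the feedback inhibitors Spry1 (0.84 ± 0.20) and Spry4 (1.27 ± 0.37), and the early response genes Egr1 (1.12 ± 0.27) and Fos (1.04 ± 0.32). Several genes, such as Dusp6, Etv5, Egr2 and Bcl6b, belong to both lists. Detected genes moved with both lists, being 561 higher in Q1.

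A further 7 lists were called at the preset correlation, and each lost its call with an estimated one. Genes of the G1/S transition had a relative median of 0.32 (44 genes, camera adjusted p = 0.000645, and 0.32 with an estimated correlation). Without preparation 3 it was 0.17 (camera adjusted p = 0.00224). The clamp loader subunit Rfc2 (1.54 ± 0.40) and the replicative helicase subunit Mcm5 (0.97 ± 0.27) passed adjusted over the list alone, and 0 over all genes (limma; 14 at an unadjusted p under 0.05). Immediate early and heat shock genes, which also respond to tissue dissociation, had 0.26 (14 genes, adjusted p = 0.00804, and 0.15 with an estimated correlation). Their relative median was 0.11 without preparation 5 (camera adjusted p = 0.102) and 0.13 without preparation 2 (adjusted p = 0.0615). With detected genes as a covariate these genes stood at 0.52 (adjusted p = 1.46e-05). Of them 5, led by the phosphatase Dusp1 (1.54 ± 0.36), passed adjusted over the list alone and 0 over all genes (limma; 5 at an unadjusted p under 0.05).

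Cytosolic ribosomal protein genes were the largest list to stand lower in Q1 (relative median -0.31, 84 genes, lower in 5 of 5 preparations). Their camera adjusted p was 4.40e-12, and the adjusted p was 0.0562 with an estimated correlation. Of them, 60 had a fitted difference below 0. The one member past the threshold adjusted over the list alone, Rpl39, went the other way (1.14 ± 0.29), and 0 passed over all genes (limma; 11 lower and 3 higher at an unadjusted p under 0.05). With each cell scaled to a common 75th percentile the unshifted median turned from -0.14 to 0.07, while the relative median stayed below 0 at -0.19. Genes of the nuclear-encoded respiratory chain had a relative median of -0.15 (77 genes, adjusted p = 0.00108, and 0.15 with an estimated correlation), although their unshifted median of 0.02 and mean of 0.05 lay above 0. At a common 75th percentile their relative median was -0.02 and the call was lost (camera adjusted p = 0.759). Their unshifted median lay at percentile 6.64 of 10000 random lists matched on expression, within the central 95%, as did that of the retinoic acid list at percentile 5.37. Also lower relative to all genes were retinoic acid response genes (-0.22, 11 genes, adjusted p = 0.0069, and 0.162 with an estimated correlation), progenitor associated genes (-0.38, 10 genes, adjusted p = 0.0342, and 0.178) and genes of differentiating spermatogonia (-0.26, 12 genes, adjusted p = 0.0423, and 0.15). Of these 3 lists only the uridine phosphorylase gene Upp1 (-1.89 ± 0.56) passed adjusted over the list alone, and 0 genes over all genes (limma). At an unadjusted p under 0.05 the progenitor list had 2 lower and 1 higher members, the list of differentiating genes 0 lower and 1 higher, and the retinoic acid list 0 of either. With detected genes as a covariate the ribosomal list (-0.08, adjusted p = 0.31), the G1/S list (0.01, adjusted p = 0.987), the respiratory chain list (-0.09, adjusted p = 0.0732) and the list of differentiating genes (-0.17, adjusted p = 0.31) lost their calls. The retinoic acid list kept its call there at -0.78 (camera adjusted p = 0.0008). It lost the call without a filter (-0.07, adjusted p = 0.0689) and with the log of the mean over cells (-0.49, adjusted p = 0.0703). The progenitor list lost its call with a pseudocount of 0.1 (camera adjusted p = 0.0775), a filter at 25% of cells (0.109) and in matched cells (0.0909). That call was also lost without preparation 1, 2, 4 or 5 (camera adjusted p from 0.117 to 0.227). The list of differentiating genes lost its call in 8 of 12 alternative fits.

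**Figure D3:**
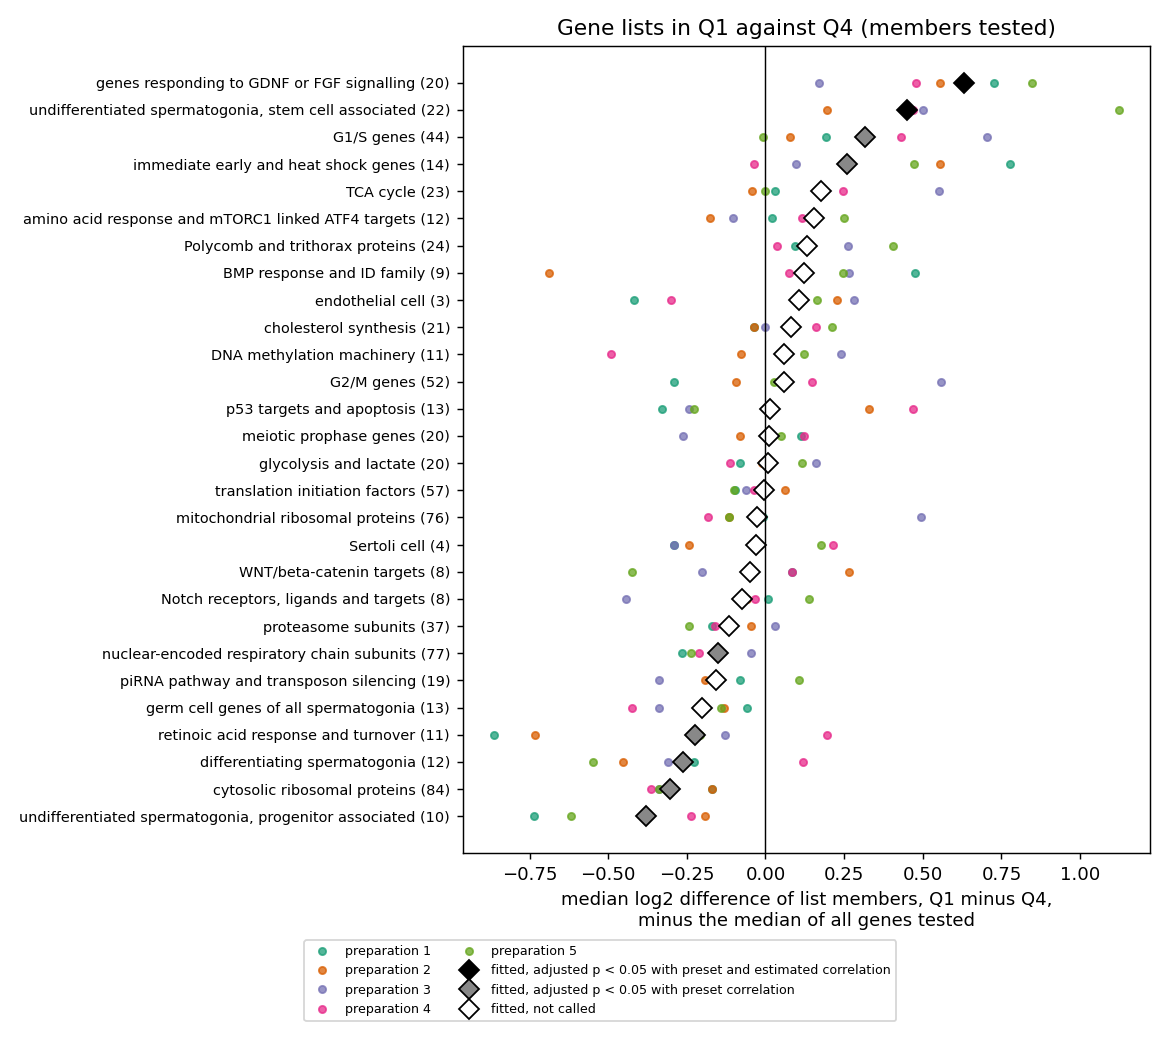
Median log2 difference (Q1 minus Q4) of each of the 28 tested gene lists minus the median of all genes; diamonds are the fitted values, dots the 5 preparations, and numbers in brackets the members tested. The GDNF or FGF list (0.63) and the stem cell associated list (0.45), in black, were the 2 called with an estimated correlation as well.

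The other 19 lists were not called (camera adjusted p from 0.176 to 0.965). They covered meiotic, germ cell, piRNA, BMP, WNT, Notch, ATF4, p53, G2/M, glycolysis, TCA cycle, cholesterol, DNA methylation, Polycomb and trithorax, Sertoli, endothelial, mitochondrial ribosome, translation initiation and proteasome genes. In 3 of them, DNA methylation, p53 and Sertoli, the relative median and the test differed in sign. The fry test asks whether a list moves one way on balance, without setting it against other genes, whose median was 0.17. It called 8 lists. Of the 9 called by camera these were the stem cell, GDNF or FGF, stress, G1/S and ribosomal lists (fry adjusted p from 0.00100 to 0.0488, the last for ribosomal proteins, lower in Q1, whose unshifted median turned to 0.07 at a common 75th percentile). The progenitor, differentiating, retinoic acid and respiratory chain lists were not called by fry (adjusted p from 0.409 to 0.875). Higher in Q1 by fry were also the TCA cycle (adjusted p = 0.0146), Polycomb and trithorax (0.0243) and translation initiation (0.0419) lists.

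The trend over the 4 quartiles asked whether expression had a linear slope with brightness. It weighs Q1 and Q4 most, so a call does not show a change at every step. The trend test called 14 genes, all higher toward Q1 (limma, 1276 at an unadjusted p under 0.05), led by Capg (0.63 ± 0.11 per quartile step, adjusted p = 0.0377), Upf3b (0.70 ± 0.13) and Rab4a (0.49 ± 0.09). All 8 genes called between Q1 and Q4 were among them, from the same cells. The other 6, chosen for naming after their values were seen, were Tcl1 (0.78 ± 0.15), Tubg2, a gamma-tubulin, Smoc2, a matricellular protein, Zfp948, a zinc finger protein, Ptbp3, a splicing regulator, and Mapk11, a p38 kinase. Tcl1 averaged 204 ± 58.9, 140 ± 15.5, 164 ± 79.5 and 91.8 ± 48.9 FPKM from Q1 to Q4 (SD, n = 5). Some other called genes did not fall at every step either. Zfp948 averaged 69.4 FPKM in Q1 and 124 in Q2, and Hlf 3.35 in Q2 and 5.47 in Q3. Genes of small p toward Q4 included Eif4ebp1 (-0.25 ± 0.06) and Uchl1, a deubiquitinase of spermatogonia (-0.19 ± 0.05), and neither passed (limma adjusted p = 0.101 and 0.117). Without the preparation block the trend called 0 genes (643 at an unadjusted p under 0.05), with detected genes as a covariate 0 (584). Without preparations 1, 4 or 5 it called 0, and without preparation 2 or preparation 3 it called 9. Of the lists, the trend called 10, and 3 of these calls held with an estimated correlation. The stem cell associated list had a relative median of 0.16 per step and the GDNF or FGF list 0.21 (camera adjusted p = 1.59e-08 and 3.64e-09; adjusted p = 0.0307 for each with an estimated correlation). Ribosomal protein genes had -0.10 (camera adjusted p = 2.02e-13; adjusted p = 0.0403 with an estimated correlation). The other 7 were the lists called with them between Q1 and Q4, other than ribosomal proteins, and the proteasome list (-0.05, camera adjusted p = 0.0486). They lost their calls with an estimated correlation (adjusted p from 0.108 to 0.307).

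Neighbouring quartiles were compared to place the differences along the brightness scale. Between Q1 and Q2 the smallest p belonged to Hlf (1.27 ± 0.29), Amot, an angiomotin of the Hippo pathway (1.29 ± 0.32), and Rgs2, a regulator of G protein signalling (0.97 ± 0.24). In the other direction it belonged to Snora78, a small nucleolar RNA (-1.24 ± 0.28), Sh3d19 (-1.10 ± 0.30) and Cetn4, a centrin (-0.76 ± 0.21). Between Q2 and Q3 they were Dedd (1.46 ± 0.32), Zfp948 (1.59 ± 0.37) and Ado (0.71 ± 0.17), and Ppp1r21 (-0.92 ± 0.24), Rnd2 (-1.09 ± 0.30) and Hipk3 (-1.08 ± 0.31). Between Q3 and Q4 they were Parp2, a DNA repair enzyme (1.22 ± 0.26), Chp1 (1.74 ± 0.38) and Cdh1 (1.28 ± 0.29), and Zfp760 (-0.85 ± 0.16), Arhgef3 (-0.99 ± 0.28) and Ulk2, an autophagy kinase (-0.95 ± 0.27). None of these 18 differences passed the limma test, which called 0 genes in each comparison. At an unadjusted p under 0.05 there were 426 genes between Q1 and Q2, 489 between Q2 and Q3 and 773 between Q3 and Q4, the last with 694 higher in Q3 and 79 lower, where chance gives 522.6. Q4 cells also had fewer detected genes than Q3 cells (5732 against 6106). With detected genes as a covariate the count between Q3 and Q4 was 521, near that of chance. The stem cell associated list had relative medians of 0.15, 0.17 and 0.26 over the 3 steps and the GDNF or FGF list 0.23, 0.23 and 0.19, and neither was called at a single step. Ribosomal protein genes were called lower in Q2 than in Q3 (-0.11, camera adjusted p = 0.0234; adjusted p = 0.735 with an estimated correlation). They were also called lower in Q3 than in Q4 (-0.20, adjusted p = 4.88e-06, and 0.731 with an estimated correlation), as were respiratory chain genes (-0.16, adjusted p = 0.0272, and 0.731), all relative to all genes. Of the 8 genes called between Q1 and Q4, 5 (62.5%) were also higher in Q2 than in Q3, whose means shared the fit and its spread with that comparison; over all tested genes 55.04% had the same sign in both. Snrpn and Snurf, which share 1 locus, lay near 0 there with opposite signs (-0.01 and 0.06), so the count of 5 includes Snurf but not Snrpn.

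Few cells held several markers of another testis cell type, while some single markers were frequent. At least 3 Sertoli cell markers at FPKM of at least 1 were found in 34 cells (12 in Q1, 9 in Q2, 8 in Q3 and 5 in Q4), at least 3 endothelial markers in 11, peritubular myoid in 6, macrophage in 4, stromal in 2, and Leydig or erythroid in 0. From Q1 to Q4 these cells numbered 3, 5, 2 and 1 for endothelial, 3, 3, 0 and 0 for myoid, 3, 1, 0 and 0 for macrophage and 0, 0, 1 and 1 for stromal markers. The mean log2 level of the erythroid markers was 0.06 ± 0.08 in Q1 and 0.01 ± 0.01 in Q4 (SD, n = 5). These differences between quartiles were not tested. Over all lists this made 57 hits at FPKM of at least 1 and 15 at FPKM of at least 10. The most frequent Sertoli list member, the transferrin gene Trf, was found in 49.6% of cells, while Amh was found in 0. The 4 tested genes of the 18 Sertoli markers were not called as a list between Q1 and Q4 (relative median -0.03, camera adjusted p = 0.965).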

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

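The tests of sequencing depth, the matched cells, the test without low cells, the shortened GDNF or FGF list, the reassignment of quartile labels among cells and the splits within preparations were chosen after the data had been seen.

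In 7 of 68 groups of 5 preparation means, 1 preparation stood far from the other 4; chance gives about 3.4. Etv5 in Q4 averaged 58.9 FPKM in preparation 1 (4 cells), against 29.2 to 33.6 elsewhere, and that preparation was the one where Etv5 was not higher in Q1. Stra8 in Q1 averaged 323 FPKM in preparation 3, against 57.8 to 96.05 elsewhere, with the gene at FPKM of at least 1 in 11 of 11 cells. Nefm in Q1 averaged 74.9 FPKM in preparation 1, against 21.5 to 36.1, in 8 of 8 cells. Neurog3 in Q2 averaged 6.47 FPKM in preparation 2, against 0 to 1.18, from 2 of 16 cells. Kit in Q2 averaged 21.96 FPKM in preparation 3, against 14.7 to 16.7, from 1 of 7 cells. Rab4a in Q2 averaged 31.1 FPKM in preparation 3, against 7.98 to 12.9, from 1 of 7 cells, and in Q4 8.44 FPKM in preparation 2, against 0 to 2.45, from 4 of 15 cells.

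The stem cell associated and GDNF or FGF lists stood higher in Q1, where more genes were detected per cell. A difference in library complexity as the whole cause is argued against by the fit with detected genes as a covariate, in which the stem cell list had a relative median of 0.55 (0.546, camera adjusted p = 4.68e-06; 0.45 without the covariate) and the GDNF or FGF list 0.68 (0.678, adjusted p = 8.60e-10; 0.63 without). Expression level of the members as the whole cause is argued against by the stem cell list's unshifted median of 0.62. It lay at percentile 100 of 10000 random lists matched on expression (the central 95% of their medians ended at 0.37). Such lists ignore correlation between genes, so the percentile overstates rarity, though the camera call held with an estimated correlation (adjusted p = 0.0342). Without the 3 genes shared with the stress list, the GDNF or FGF list kept its call (17 genes, relative median 0.45, camera adjusted p = 3.72e-06). Its shift thus did not rest on those 3 genes alone. An immediate early response to dissociation stays open, since it could also raise other members. The stress list itself stood at 0.52 with the covariate (camera adjusted p = 1.46e-05). The lists share members, Id4 is in the stem cell list and drives the reporter, and no biological explanation was tested.

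Cytosolic ribosomal protein genes stood lower in Q1. Shares of abundant transcripts that rise where fewer genes are detected would raise all abundant genes in Q4 alike. Against this as the whole cause, random lists matched on expression had medians above 0, with a central 95% that began at 0.05. The ribosomal list's unshifted median of -0.14 lay at percentile 0 of 10000 such lists. They ignore correlation between genes, estimated at 0.10 in this list, so the percentile alone excludes no chance shift of the list. Library complexity stays open: with detected genes as a covariate the relative median went from -0.31 to -0.08 (-0.081, adjusted p = 0.31), so the call ended with a smaller size, while in Q1 and Q4 cells matched on detected genes it was -0.15 (adjusted p = 0.00284), though matching left Q1 with 127, 137 and 161 more detected genes in preparations 2, 3 and 5 and rested on 3 pairs each in preparations 1 and 3. A biological difference in ribosomal protein expression along EGFP brightness may add to it and was not told apart from complexity, which moves with the quartiles.

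More genes were detected per cell in Q1, and far more genes leaned toward Q1 than away from it. Depth as the whole cause is argued against by preparations 3 and 4, where Q1 cells had fewer fragments than Q4 cells (ratios 0.979 and 0.948) and the gaps were the largest of the 5 (1071 and 717 genes), and a few poor libraries by a gap of 460 ± 256 without the 4 lowest cells. Adjusting each cell for its log2 fragments gave a gap of 594 ± 338 (SD, n = 5), but the fitted slope was negative (-305 genes per doubling), so the adjustment could only widen the mean gap, and it was chosen after an earlier test, on the log2 ratio of fragments (0.09 ± 0.18), had met neither of its bounds. Of genes at an unadjusted p under 0.05, 90.9% were higher in Q1, 63.2% of 793 in matched cells, where that gap in part remained, and 52.2% of 563 with the covariate. The bound set beforehand, more than 10 points above 50% in matched cells, was met, which would have argued against fewer detected genes in Q4 as the whole cause, but the covariate fit falls on the other side of it, so the lean and the lower number of detected genes in Q4 cannot be told apart here, and no biological explanation was tested.

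Chance was weighed by other splits of the same means. Of 100 splits of the 10 means of Q1 and Q4, the real one included, 1 gave as many called genes (8; highest other 5) and 2 gave as many called lists (9; highest other 10). These splits ignore the pairing by preparation, so no exclusion of chance is drawn from them for either count. For the trend, 1 of 100 orders of the quartiles within preparations gave as many (14; highest other 1). For Q1 against Q2, Q2 against Q3 and Q3 against Q4, where 0 genes were called by limma (426, 489 and 773 at an unadjusted p under 0.05), 100 of 100 splits gave at least as many (highest other 0, 1 and 3). Every split matches a count of 0, so these splits decide nothing. Among the 16 splits that exchange Q1 and Q4 within preparations, too few for a share under 0.05, 1 gave 8 genes (highest other 0) and 2 gave 9 or more lists (highest other 10). When quartile labels were reassigned 100 times among the cells of each preparation, at most 1 gene and 5 lists (median 1) were called, and the relative medians stayed within -0.30 to 0.22 for the stem cell list, -0.32 to 0.20 for the GDNF or FGF list and -0.16 to 0.19 for ribosomal proteins.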

How the results depend on the processing

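The matched cells and the fit without the Sertoli-rich cell were chosen after seeing the data. For Q1 against Q4, no called list reversed by camera and no named gene that passed reversed by limma. Of named genes that did not pass, 2 changed sign. Zbtb16 (0.50) ran from -0.24 to 0.79 over the alternatives. Kit (-0.03) ran from -1.15 to 0.06, and up to 0.19 with a preparation left out. List calls by fry, in the trend and between neighbouring quartiles were not run under the alternatives. Counts of called genes moved most. Fewer preparations or cells, or more genes tested, take calls away by construction. Scaling to a common 75th percentile, taken over values above 0, lowers Q4 against Q1 by construction. The mean of that percentile was higher in Q4 in each preparation, by little in preparation 2 (66.5 against 62.8) and most in preparation 3 (165 against 102). The cause was not tested further. For Q1 against Q4 (8 genes), limma called 0 without a filter, with the log of the mean over cells, with equal weights, without the preparation block, with detected genes as a covariate, without the 4 low cells, in matched cells, and with only the 2 quartiles fitted, and 44 (all 8 among them) with cells scaled to a common 75th percentile. Unadjusted counts under 0.05 in these settings include 1571 without a filter, 863, 1106, 592 without the block, 563, 1090 and 793 in matched cells. For the trend (14 genes) it called 0 in the same settings that apply, 25 with cells rescaled to a common total and 64 at a common 75th percentile, all 14 among both. Between Q3 and Q4, 1 gene was called without a filter. Leaving out 1 preparation gave 0 to 11 genes for Q1 against Q4, 0 to 9 for the trend, 0 for each neighbouring pair, and 5 to 11 lists, with 5 without preparation 2 or 5. Without the preparation block differentiating genes lost their call between Q1 and Q4 (-0.29, adjusted p = 0.125) and the other 8 lists kept theirs; lists of other comparisons were not run without it. Of 9 lists, 5 were called with the covariate and 2 with an estimated correlation; ribosomal proteins then had -0.081 (adjusted p = 0.31) and -0.31 (adjusted p = 0.0562), with adjusted p from 1.58e-14 to 0.31 over the alternatives. The stem cell list (0.35 to 0.76) and the GDNF or FGF list (0.45 to 1.14) kept their calls in every alternative, and without each preparation they ran from 0.38 to 0.50 and from 0.55 to 0.65. The median of all genes was 0.17, and 0.26 at a common 75th percentile, 0.32 with a pseudocount of 0.1, 0.06 with the log of the mean, 0.02 in matched cells and -0.02 with the covariate, so list values are given relative to it. The share of genes at an unadjusted p under 0.05 that were higher in Q1 was 90.9%, and 65.4% with the log of the mean. Hits of other cell types, 57 at FPKM of at least 1, were 15 at FPKM of at least 10. Gaps in detected genes were 456 to 603. Tests on counts (edgeR, DESeq2) were not run, since whole reads could not be recovered. At these depths a gene missed in a cell may be undetected, not absent. In simulation limma found 10% of 2-fold changes, but values of 0 stayed 0 there, so missed molecules were not simulated.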

Other observations

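The tests of chromosome X, of the Sertoli-rich cell and of the neighbours of Upf3b were chosen after the data had been seen, and genes named here that no rule fixed were chosen after their values were seen.

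Among 23 TCA cycle genes, 4 passed when adjusted over the list alone and 0 over all genes (limma; 6 higher and 1 lower at an unadjusted p under 0.05): Dlst of the 2-oxoglutarate dehydrogenase complex (1.75 ± 0.39), Pdha1 of pyruvate dehydrogenase (1.6 ± 0.37), Idh3g of isocitrate dehydrogenase (1.35 ± 0.40) and Dld, which serves several of these complexes (0.85 ± 0.28). The list was not called against other genes (relative median 0.18, higher in 3 of 5 preparations, camera adjusted p = 0.187), while fry, which does not set it against them, called it (adjusted p = 0.0146). Single members of other uncalled lists that passed adjusted over the list alone were the BMP receptor Bmpr1a (1.33 ± 0.34), asparagine synthetase Asns (1.64 ± 0.48), the aldolase Aldoc (1.47 ± 0.43) and, lower in Q1, Eif4ebp1 (-0.76 ± 0.19); 0 of them passed over all genes (limma adjusted p from 0.136 to 0.176).

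The Q3 cell of preparation 2 with the most Sertoli markers had 13 of the 18 at FPKM of at least 1, against 5 in the next highest cell. It held Clu at 886 FPKM, Cst12 at 372, Inha at 262, Gstm6 at 206 and Defb19 at 146, with Trf listed at 0, and all 13 germ cell markers, with 7282 detected genes. Per the labels, wells with multiplets were left out after imaging. Without that cell the relative medians of the 3 leading lists moved by at most 0.000882, and 8 and 14 genes were again called. As a Q3 cell it enters Q1 against Q4 only through the preparation block, the shared spread and the filter. The unchanged lists and 8 calls were therefore close to given by construction.

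Upf3b lies on chromosome X, which prompted a test of whether genes of that chromosome move together in Q1. The 386 tested genes of chromosome X had a median difference of 0.24, against 0.17 over all genes, at percentile 99.95 of 10000 random lists matched on expression, and the chromosome's median was above that of all genes in 4 of 5 preparations. By the bound set beforehand this would fit such a shift, but random lists ignore correlation between genes, and camera, which was looked at afterwards, gave p = 0.218 with the preset and p = 0.326 with an estimated correlation. Whether chromosome X genes may shift as a set cannot be told apart from correlated chance. Rpl39, 6275 bases from Upf3b on the same strand, differed by 1.14 ± 0.29 (5 of 5 preparations higher, limma adjusted p = 0.132), while Nkap, Ndufa1 and Gm9, within 100000 bases, differed by 0.57 ± 0.31, -0.03 ± 0.22 and 0.80 ± 0.37 (higher in 4, 3 and 5 of 5 preparations), and none of these 3 passed (limma adjusted p from 0.406 to 0.979).

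By expression level, the lean toward Q1 was present in each of 4 equal groups of 2613 genes: 63.5%, 67.7%, 75.8% and 70.95% of genes were higher in Q1, from the lowest to the highest mean expression.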
